A study of Homo sapiens with 12 samples.

How the data were processed

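MDA-MB-231 cells were left untreated or irradiated with 2 Gy of X-rays and lysed 6 h later, and RNA bound to eIF4E was collected with an antibody and a commercial RIP-chip kit, with IgG as the control, per the labels' protocols. The RNA of each precipitate was hybridised to 1 Affymetrix array, 12 in all. Titles in the labels give each array's group and replicate number, 3 arrays in each of 4 groups, and the series' design text speaks of 3 biological replicates.

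The deposited table holds 1 signal per probe set and array, an intensity on a linear scale, and per the submitters' processing notes the authors used MAS5, whose version is not given in the sources used here. The trimmed mean (2% left out at each end) of each array's deposited signal was 500.2, so the values are relative within an array and hold no absolute amount of RNA. How much RNA was labelled, whether it was amplified and how much control RNA was added is not given in the sources used here. Signals were used as deposited, with no further normalization. Scan dates were not used here.

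Of 22277 probe sets, 62 were controls. Of the platform annotation's entries, 19064 probe sets had 1 gene symbol, 1043 had several and 2108 had none, and the symbols of 19052 were updated through their gene identifier to the RefSeq table of GRCh38.p14. That assembly was used for names and gene lengths only, since the array's annotation names no build, and no coordinates are given. Probe sets with several genes or none were left out of the gene tests. Each of 11963 genes was represented by the probe set with the highest mean, those ending in _x_at only where there was no other, and genes whose mean log2 signal was under the 40th percentile (a signal of 57.4) were left out, which kept 7178. Where a gene had several probe sets above the filter (2317 genes), all were compared. The 664 probe sets with no gene and above the same filter were tested separately.

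Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on log2(signal + 16), with 4 group means over all 12 arrays, and adjusted with Benjamini-Hochberg over the genes tested at a threshold of 0.05. A difference on this scale understates the change of dim genes. Errors of log2 differences are the fit's SE and errors of signals are SD. The comparisons were eIF4E against IgG in untreated cells, in irradiated cells and as their mean, irradiated against untreated cells within each antibody, and the difference of both irradiation effects. Of 30 gene lists, 26 had at least 5 tested members and were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with the correlation estimated from the data beside it. Members were also adjusted over the list alone. Array measures were compared with exact two-sided permutation tests of geometric means. Figures were drawn with matplotlib 3.10.9.

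The design, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, in each comparison, up to 10 genes in each direction with the largest change among those past the threshold whose arrays do not overlap. Where fewer than 5 passed, it takes those with the smallest p up to 5, stated as not past the threshold. It adds up to 2 members at either end of each list and 16 fixed genes, of which 1 is not reported here. The genes named with a gene family in the other observations, and RNASEH1 and CTSV, were chosen after their values were seen.

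The replicate number was tested as a pairing by correlating, over genes, the deviations of same-numbered arrays from their group means. Untreated and irradiated eIF4E arrays correlated at 0.374, 0.208 and 0.181 for numbers 1, 2 and 3. They were treated as paired on this evidence from the data, since the labels say nothing of shared cultures or days. The check cannot tell pairs from a replicate 1 set apart in both groups. Deviations within a group cancel out, so such a replicate 1 would also make numbers 2 and 3 correlate. Differently numbered arrays were not compared. In each of the other 5 pairs of groups at least 1 number was under 0.1. The alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, no variance trend, array quality weights, the replicate block, only the groups compared, probe set means, each probe set by itself, a 1.5-fold minimum and the omission of each array.

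The fitting steps were tested on simulated data of 7178 genes with the real arrays' spread. Known changes were set in at most 67 genes at each fold size, and 1 list of 50 genes was shifted by 0.3. In the real data 5078 genes passed for the mean antibody comparison, which changes the adjusted threshold. The shares below hold only for the few genes changed in the simulation and do not describe the antibody comparisons. The simulated noise was independent between arrays and held no structure by replicate number. For irradiation in eIF4E the shares therefore leave out the pairing seen in the real arrays. For eIF4E against IgG in untreated cells, 22.4% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 100% of those changed 4-fold were recovered. In irradiated cells these shares were 41.8%, 83.3% and 100%, and for the mean of both 67.2%, 100% and 100%. For irradiation in eIF4E they were 26.9%, 79.7% and 100%, in IgG 34.3%, 81.8% and 100%, and for the interaction 8.96%, 38.8% and 95.5%. In the IgG simulation 20.2% of the called genes had not been changed.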

Results

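RNA that co-precipitated with eIF4E, the protein that binds the cap of messenger RNAs and starts their translation, was measured in MDA-MB-231 cells, a human triple-negative breast cancer line. Cells were untreated or had received 2 Gy of X-rays 6 h before collection, and each lysate was precipitated with an antibody to eIF4E or with control IgG, which gives the background. The 12 arrays form 4 groups of 3: untreated IgG, irradiated IgG, untreated eIF4E and irradiated eIF4E. The design text calls the replicates biological. Of 11963 genes with a probe set of their own, 7178 were bright enough to be tested. Log2 values correlated at 0.956 to 0.969 within IgG groups and at 0.977 to 0.986 within eIF4E groups, and 0 pairs of arrays held identical values. The precision of each value is limited by the number of arrays.

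The arrays of both antibodies differed in their control probe sets, whatever the treatment. Signal of the Alu probe set, which detects a repeat found in introns and intergenic DNA, was 36876 to 53246 on the 6 IgG arrays and 13482 to 18476 on the 6 eIF4E arrays, a 2.70-fold difference of geometric means (exact permutation test, two-sided, p = 0.00216, the smallest that 6 arrays against 6 allow). The ratio of the 3' to the 5' probe set of actin, which rises as RNA is degraded or copied incompletely, was 2.96 to 5.38 with IgG and 1.33 to 1.53 with eIF4E, and the GAPDH ratio was 2.03 to 2.78 with IgG and 1.13 to 1.31 with eIF4E (exact p = 0.00216 for each). Poly-A control transcripts, added to RNA before labelling, were at least 65.9-fold brighter on IgG arrays by geometric mean. On eIF4E arrays their geometric mean of 22.0 was near the 14.8 of genes not expressed in this cell type, so the fold is a lower bound. Those genes are the liver, leukocyte and neuron or muscle markers, taken by their median on each array. Their lack of expression was assumed and not tested. An SD given with them is over the medians of arrays and not over genes. Hybridization controls, added to labelled RNA, were 5.62-fold brighter (exact p = 0.00216 for each). Every array had been scaled to 1 trimmed mean, so each change given here is relative to the other genes of the array. Rescaling to the hybridization controls moved every gene by 2.49 on the log2 scale towards eIF4E, and rescaling to the poly-A controls by at least 6.22 in untreated and 5.86 in irradiated cells, so higher and lower hold only relative to the other genes. The ratio of bioB to bioC, both hybridization controls, set replicate 1 of every group (0.373 to 0.443) apart from replicates 2 and 3 (0.0269 to 0.0523).

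**Figure D1:**
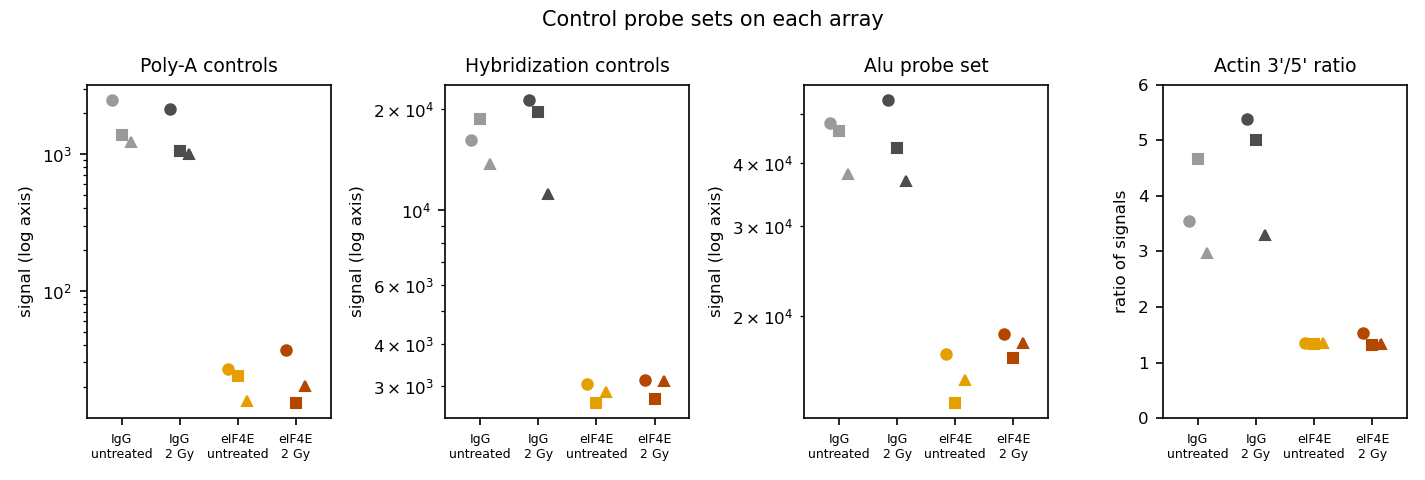
Signal of the poly-A controls, the hybridization controls and the Alu probe set (log axes) and the actin 3'/5' ratio (linear axis) on each of the 12 arrays by group, with a circle, square or triangle for replicate 1, 2 or 3. All 6 IgG arrays lie above all 6 eIF4E arrays in each panel, and the geometric means differ at least 65.9-fold for the poly-A controls, which are near background on eIF4E arrays, and 2.70-fold for Alu.

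The comparison of eIF4E with IgG asks which RNAs were recovered with eIF4E above background. Averaged over untreated and irradiated cells, the largest relative increases were those of DCXR, a carbonyl reductase, and BANF1, a DNA-binding protein of the nuclear envelope. DCXR was higher by 3.17 ± 0.21 (log2, SE, 6 arrays a side, adjusted p = 2.48e-09 by limma), with a signal of 207 ± 23.7 in untreated IgG and 1728 ± 281 in untreated eIF4E (SD, n = 3). BANF1 was higher by 3.03 ± 0.12 (adjusted p = 6.13e-11), with 506 ± 25.1 in untreated IgG and 4707 ± 614 in untreated eIF4E. ILK, a kinase of integrin adhesions, was higher by 2.91 ± 0.13 and TOMM22, a receptor of the mitochondrial protein import pore, by 2.77 ± 0.15 (adjusted p = 1.49e-10 and 2.96e-10). The largest decreases were those of TMF1, a Golgi coiled-coil protein, at -2.54 ± 0.11 (adjusted p = 1.26e-10, with 1868 ± 123 in untreated IgG and 307 ± 57.0 in untreated eIF4E), and of NOTCH2NLA, one of a family of near-identical copies whose signal is uncertain for that reason, at -2.50 ± 0.19. Also lower were SRRM2, a spliceosome scaffold (-2.37 ± 0.19), EIF5B, the GTPase that joins ribosomal subunits (-2.31 ± 0.19), and TPR, which forms the nuclear pore basket (-2.29 ± 0.17). The naming rule took only genes in which all 6 eIF4E arrays lay on one side of all 6 IgG arrays. The changes called largest are therefore the largest among such genes. The other genes among the 10 largest changes in each direction were PCGF1, LY6E, FLOT1, GSTM4, PCBD1 and ERI3, higher by 2.72 to 3.03, and PTPRO, PANK3, MID1, RBBP6 and NKTR, between -2.49 and -2.23.

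With limma, 5078 of the 7178 genes passed an adjusted p of 0.05, 2334 higher and 2744 lower with eIF4E. Of these, 882 and 999 also differed at least 2-fold. With quantile normalization the split was 2545 higher and 2459 lower, and with arrays centred on their median it was 2704 and 2332. In 3579 genes (49.9%) the 6 arrays of one antibody did not overlap those of the other. In untreated cells alone 4230 genes passed (1954 higher, 2276 lower), and the arrays did not overlap in 4790 (66.7%, where chance gives 10%). There FLOT1, a scaffold of membrane rafts, was higher by 3.31 ± 0.41. Its signal in untreated IgG (39.7 ± 41.1), like that of PCGF1 (32.5 ± 26.5), GSTM4 (52.4 ± 57.2) and ERI3 (57.4 ± 36.8), was not clear of that of genes not expressed in this cell type (24.5 ± 7.66), so these sizes depend on the pseudocount. PTPRO, a receptor tyrosine phosphatase, had the largest decrease (-2.71 ± 0.44, n = 3 a side). In irradiated cells 4273 passed (1951 higher, 2322 lower; 4478 without overlap, 62.4%), led by DCXR (3.38 ± 0.30) and NOTCH2NLA (-2.90 ± 0.26). Without replicate 1 of every group, which the bioB to bioC ratio sets apart, the counts were 4343, 4095 and 5029 for untreated, irradiated and both; the replicate 1 arrays are 1 per group and allow no test of their own. Of 1419 genes with more than 1 called probe set, 234 (16.5%) had probe sets called in opposite directions, among them CALR, CD44, SRSF6 and ZNF207.

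**Figure D2:**
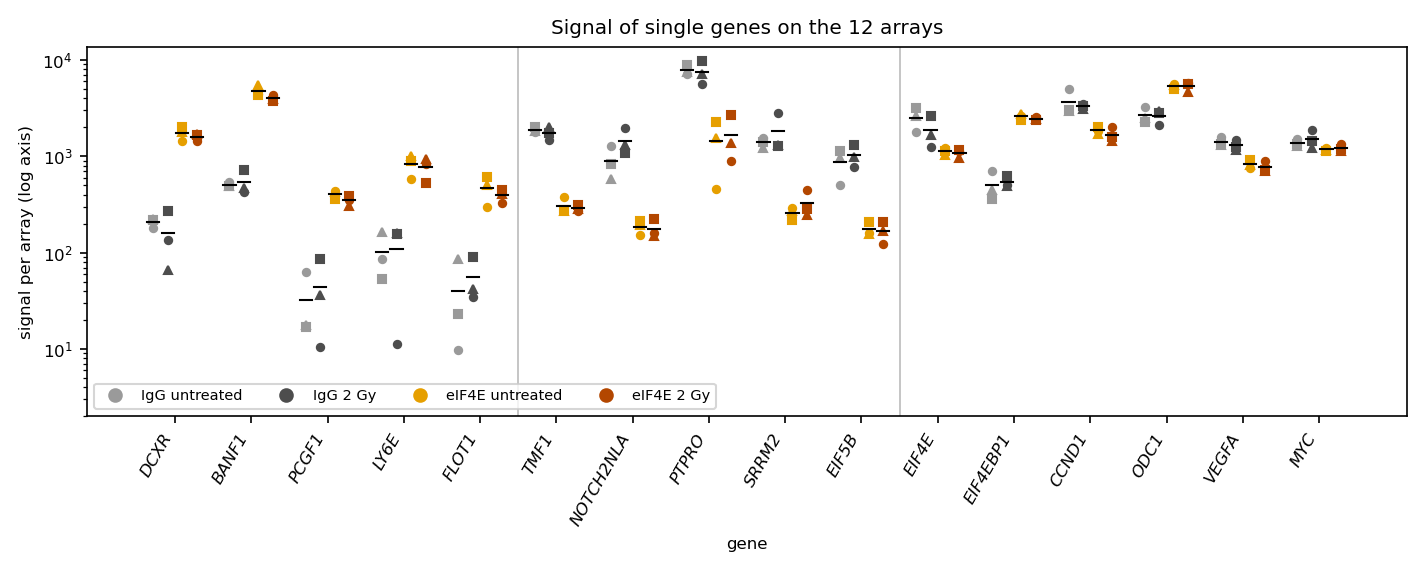
Signal (log axis) of 16 genes on each of the 12 arrays by group, with a black bar at the group mean. BANF1 lies at 506 in untreated IgG and 4707 in untreated eIF4E, and TMF1 at 1868 and 307; all signals are as deposited and scaled within arrays.

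Genes of the cap-binding complex and messenger RNAs often described as sensitive to eIF4E were fixed in advance. EIF4EBP1, the repressor that binds eIF4E, was higher with eIF4E by 2.27 ± 0.14 (adjusted p = 9.28e-10), while EIF4E itself was lower (-0.91 ± 0.16, adjusted p = 9.95e-05), as was its partner EIF4G1 (-0.82 ± 0.12, adjusted p = 1.26e-05). ODC1, which starts polyamine synthesis, was higher (1.03 ± 0.11, adjusted p = 5.74e-07), and CCND1, the cyclin of the G1 phase, was lower (-0.96 ± 0.13, adjusted p = 4.97e-06). BRCA1, a DNA repair gene, was lower (-1.16 ± 0.14, adjusted p = 1.74e-06). As the mean of its probe sets it was at -0.17 in untreated cells alone and lost its call there (adjusted p = 0.625). BIRC5, an inhibitor of apoptosis, was higher (0.43 ± 0.13, adjusted p = 0.00729), though its IgG and eIF4E arrays overlapped. VEGFA, the angiogenic growth factor, was lower by its brightest probe set (-0.74 ± 0.11, adjusted p = 1.10e-05) but at 0.16 (adjusted p = 0.252) as the mean of its probe sets. MYC, a transcription factor, was at -0.25 ± 0.11 (adjusted p = 0.0459) and lost that call after median centring (-0.12, adjusted p = 0.356). With its value still at -0.25, it also lost the call after quantile normalization (adjusted p = 0.0619), with no filter on dim probe sets (0.0550), without a variance trend (0.0613) and with every probe set tested by itself (0.0505). The call was lost in 9 of the 12 omissions of 1 array (adjusted p from 0.0515 to 0.105), those of untreated IgG replicates 1 and 2, irradiated IgG replicates 1 and 2, every untreated eIF4E replicate and irradiated eIF4E replicates 2 and 3. CDKN1A, the cell cycle inhibitor induced by p53, was at 0.40 ± 0.18 (adjusted p = 0.0580) and passed after quantile normalization (0.48, adjusted p = 0.0350) and centring (0.53, adjusted p = 0.0179), with array quality weights (0.42, adjusted p = 0.0166) and without untreated IgG replicate 1 (adjusted p = 0.0104), irradiated IgG replicate 1 (0.0322) or irradiated eIF4E replicate 2 (0.0204). CHEK1, a checkpoint kinase, was at -0.03 ± 0.11 (adjusted p = 0.844) and was above 0 with either scaling. ACTB was at 0.14 ± 0.15 (adjusted p = 0.435) and passed after quantile normalization (0.56, adjusted p = 0.00107) and without irradiated IgG replicate 2 (0.30, adjusted p = 0.0183), whereas GAPDH was lower (-0.47 ± 0.13, adjusted p = 0.00304) and lost the call after it (-0.07, adjusted p = 0.367). The control probe sets of both genes differed by position. GAPDH was at 0.36 at its 5' end and -0.59 at its 3' end (exact permutation test, p = 0.00433 and 0.00216). Actin was at 1.91 and 0.36. The direction for GAPDH therefore depended on the place of the probe set. MDM2 lay under the signal filter, and MALAT1 had no probe set of its own.

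Oxidative phosphorylation genes, the subunits of the mitochondrial respiratory chain and ATP synthase, were relatively higher with eIF4E: 44 of 50 tested members were higher and 3 lower, with a median of 0.89 (camera, adjusted p = 1.52e-10; adjusted p = 0.456 with an estimated correlation). ATP5F1D and ATP5MC1 rose by 2.25 ± 0.13 and 2.10 ± 0.11, while NDUFS1 (-0.95) and ATP5F1A (-0.67) fell. Replication-dependent histones, whose messengers end in a stem-loop without a poly-A tail, were higher in 10 of 12 members and lower in 0 (median 0.75, adjusted p = 0.00625; adjusted p = 0.456 with an estimated correlation), with H1-2 at 1.83 ± 0.10 and H2AC14 at 1.86 ± 0.31. The signal of H2AC14 in untreated IgG (52.9 ± 64.5) was not clear of that of genes not expressed in this cell type (24.5 ± 7.66), so its size depends on the pseudocount. Histone copies are near-identical, so single members are uncertain. Proteasome subunits were higher in 16 members and lower in 4 of 27 (17 and 4 adjusted over the list alone; median 0.47, adjusted p = 0.00625; adjusted p = 0.456 with an estimated correlation), from PSMC4 at 1.69 to PSMD1 at -1.30. The 3 lists moved with the lower Alu signal and the lower actin 3'/5' ratio of the eIF4E arrays. These measures separate the same arrays as the antibody, so any list apart by antibody moves with them.

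Mesenchymal and matrix genes, which mark the invasive state of these cells, were relatively lower with eIF4E in 21 of 31 members and higher in 5 (median -1.0, adjusted p = 0.00755; adjusted p = 0.502 with an estimated correlation). ZEB1, a repressor of epithelial genes, fell by 2.05, and CD44, a hyaluronan receptor whose probe sets went both ways, by 2.09, while MYL9, a myosin light chain, rose by 2.00 ± 0.18. C2H2 zinc finger transcription factors were lower in 22 of 35 members and higher in 2 (median -0.48, adjusted p = 0.00625; adjusted p = 0.456 with an estimated correlation), with ZNF292 at -2.08, ZNF91 at -1.88 and ZNF226 at 1.24. ZNF207, the other higher member, was at 0.40 and at 0.03 (adjusted p = 0.795) as the mean of its probe sets. Both lists moved with the higher Alu signal and 3'/5' ratios of the IgG arrays, as any list apart by antibody does. These 5 lists passed in untreated and in irradiated cells as well, with adjusted p of 1.34e-10 and 5.17e-11 for oxidative phosphorylation, 0.0119 and 0.00622 for histones, 0.00658 and 0.00638 for the proteasome, 0.0113 and 0.00622 for mesenchymal genes and 0.0119 and 0.00638 for zinc fingers. None passed there with an estimated correlation (smallest adjusted p = 0.495 in untreated and 0.376 in irradiated cells). At the preset correlation they kept sign and call under quantile normalization, under centring and with any 1 array left out.

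Ribosomal protein genes were lower with eIF4E in 31 of 53 members and higher in 4 (median -0.30, adjusted p = 0.0185; adjusted p = 0.751 with an estimated correlation), but after quantile normalization their median was 0.03 with 16 higher and 15 lower (adjusted p = 0.932), and after centring it was -0.17 (adjusted p = 0.0844). RPLP2 (-1.80 ± 0.24) and RPL27A (-1.60 ± 0.18) had the lowest values and RPL36 (1.14 ± 0.12) and RPL29 (0.53 ± 0.14) the highest. The list passed in untreated cells (29 lower, 1 higher, median -0.38, adjusted p = 0.00658; adjusted p = 0.740 with an estimated correlation) and not in irradiated cells (20 lower, 3 higher, median -0.26, adjusted p = 0.137), and quantile normalization brought these medians to 0.04 and 0.03. The call was lost without untreated IgG replicate 1 (adjusted p = 0.0632 over both treatments, 0.0607 in untreated cells) and without untreated eIF4E replicate 2 (adjusted p = 0.0560 over both treatments), and in irradiated cells it was gained without irradiated IgG replicate 3 (adjusted p = 0.0360). The list moved with the same control probe sets as the others, as any list apart by antibody does.

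Mitosis genes lay just outside the threshold, with 25 of 45 members lower and 11 higher (median -0.46, adjusted p = 0.0596; adjusted p = 0.533 with an estimated correlation), from CENPA, the centromeric histone, at 1.97 to MKI67, the proliferation marker, at -2.04. At the preset correlation, the one used for each of these alternatives, the list passed after quantile normalization (adjusted p = 0.0244), without replicate 1 of every group (adjusted p = 0.0482) and without irradiated IgG replicate 2 (adjusted p = 0.0344) or irradiated eIF4E replicate 1 (adjusted p = 0.0458). For the other 19 tested lists, camera put none past the threshold over both treatments, though many members passed one by one. Translation factors had 19 lower and 8 higher of 35 (median -0.36, adjusted p = 0.228), with EIF5A at 2.08 and EIF3A at -1.69. Messengers named in textbooks as sensitive to eIF4E had 10 lower and 7 higher of 22 (median -0.13, or 0.004 after centring, adjusted p = 0.882), with the cyclin CCND3 at 1.31 and the survival factors BCL2 at -1.54 and MCL1 at -1.0.

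Among DNA damage lists, homologous recombination and Fanconi anaemia genes had 16 lower and 4 higher of 29 (median -0.37, adjusted p = 0.252), from RPA3 at 1.80 to the kinase ATR at -1.96. End joining genes had 5 lower (6 adjusted over the list alone) and 2 higher of 9 (median -0.63, adjusted p = 0.371), with MDC1 at -1.69 and H2AX at 0.88. Excision and mismatch repair genes had 12 lower and 8 higher of 29 (median -0.21, adjusted p = 0.947), with ERCC1 at 1.68 and MSH6 at -1.34. Checkpoint genes had 8 lower and 7 higher of 20 (9 and 8 adjusted over the list alone; median -0.13, or 0.003 after centring, adjusted p = 0.882), with RAD1 at 1.15 and CDC25A at -0.80. DNA replication genes had 18 lower and 11 higher of 45 (median -0.04, above 0 with either scaling, adjusted p = 0.947), with GINS2 at 1.46 and TOP2A at -1.98. Targets of p53 had 7 lower and 7 higher of 20 (median 0.13, adjusted p = 0.671), with BAX at 1.64 and POLH at -1.02.

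In the stress and signalling lists, NF-kB targets had 4 lower and 3 higher of 13 (3 and 3 adjusted over the list alone; median -0.004, mean 0.04, the median above 0 with either scaling, adjusted p = 0.966), with RELB at 1.47 and NFKB1 at -0.63. Interferon-stimulated genes had 10 higher and 8 lower of 25 (median 0.09, adjusted p = 0.356), with IFI27 at 1.69 and RIGI at -0.96. Endoplasmic reticulum chaperones had 9 higher (10 adjusted over the list alone) and 8 lower of 24 (median -0.0003, above 0 with either scaling, mean -0.04, adjusted p = 0.982 for a shift upwards), with the chaperone CANX at -1.57 and CALR at 1.46 by its brightest probe set and 0.18 (adjusted p = 0.173) as the mean of its probe sets. Heat shock proteins had 9 lower and 1 higher of 20 (median -0.24, adjusted p = 0.228), with HSPB1 at 1.98 and HSPH1 at -1.76. In irradiated cells alone the heat shock list passed after quantile normalization (adjusted p = 0.0421). As deposited, its adjusted p there was 0.177, and adjusted p = 0.686 with an estimated correlation. Immediate early genes had 11 lower and 5 higher of 21 (median -0.24, adjusted p = 0.536), with JUNB at 1.39 and DUSP4 at -1.66. In untreated IgG the signals of RELB (50.03 ± 36.6) and JUNB (36.9 ± 32.0) were also near those of genes not expressed in this cell type. Growth factor receptor and PI3K genes had 13 lower and 8 higher of 26 (median -0.32, adjusted p = 0.536), with AKT1 at 1.82 and EGFR at -1.62. Apoptosis genes had 13 higher (14 adjusted over the list alone) and 7 lower of 28 (median 0.43, adjusted p = 0.228), with BAD at 1.81 and APAF1 at -1.19. Glycolysis and hypoxia genes had 16 lower and 7 higher of 27 (median -0.38, adjusted p = 0.285), with PKM at 1.72 and SLC2A3 at -1.44. Sterol synthesis genes had 6 higher and 3 lower of 16 (median 0.16, adjusted p = 0.536), with PMVK at 1.14 and LSS at -1.31. Spliceosome genes had 21 lower and 13 higher of 39 (median -0.45, adjusted p = 0.510), with SNRPB at 1.62 and PRPF8 at -1.65. Luminal and epithelial markers had 7 higher and 3 lower of 13 (median 0.30, adjusted p = 0.285), with KRT7 at 1.34 and ERBB3 at -0.69. The lists of nuclear RNAs and of leukocyte, liver and neuron or muscle markers had 1, 3, 2 and 2 members above the filter and were not tested; their median signals were 23.3, 17.6, 17.4 and 17.4 with IgG and 25.7, 16.3, 18.2 and 13 with eIF4E.

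**Figure D3:**
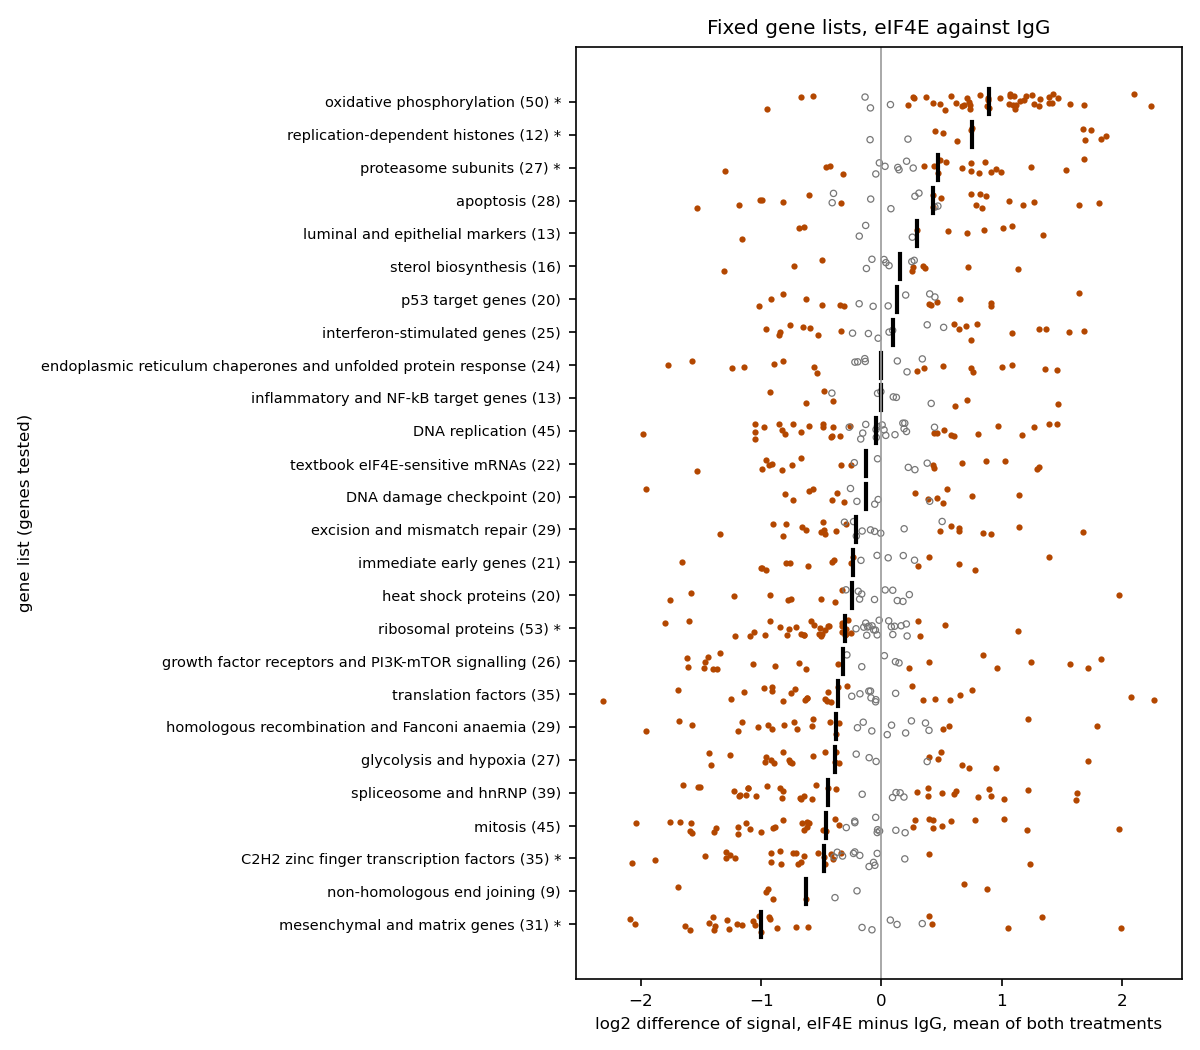
Log2 difference of eIF4E against IgG, relative to the other genes, for each member (dots; filled where adjusted p was under 0.05) of 26 gene lists, with the list median as a black bar and an asterisk for lists past the camera threshold. Oxidative phosphorylation has a median of 0.89 and mesenchymal genes of -1.0, and the ribosomal protein median of -0.30 becomes 0.03 after quantile normalization.

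The antibody differences of untreated and irradiated cells, which share no arrays, were close to each other. Across the 7178 genes, which are not independent replicates, the log2 differences correlated at r = 0.938 (Spearman rho = 0.938), and 90.4% had the same sign. Of the genes past the threshold, 1701 were higher in both and 1980 lower in both, where independent lists would share 531 and 736, and 0 were called in opposite directions. BANF1 was at 3.17 ± 0.17 in untreated and 2.89 ± 0.17 in irradiated cells, and TMF1 at -2.56 ± 0.16 and -2.52 ± 0.16.

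Irradiated and untreated cells within the eIF4E precipitates were compared to find RNAs whose share in the precipitate changed 6 h after 2 Gy. The smallest p among the increases was that of RAD54L2, a helicase of the SNF2 family, at 1.31 ± 0.34 (unadjusted p = 0.00124 by limma, n = 3 a side), with a signal of 13.9 ± 5.80 before and 57.9 ± 13.4 after, and it did not pass the adjustment. Its signal before was not above that of genes not expressed in this cell type (14.6 ± 1.06), so the size depends on the pseudocount. UBXN4, a factor of endoplasmic reticulum protein degradation, was at 0.46 ± 0.14. Among the decreases, CCNG2, a cyclin linked to growth arrest, was at -0.93 ± 0.26, and CIC, a transcriptional repressor, at -1.28 ± 0.36, and neither passed. CDKN1A was at -0.07 ± 0.26, MYC at 0.05 ± 0.15 and EIF4E at -0.07 ± 0.23. With limma 0 of 7178 genes passed, and the smallest adjusted p was 1.00. An unadjusted p under 0.05 was found in 82 genes, where chance gives 359. The shared spread gave a median SE of 0.194, against 0.152 from these 6 arrays alone. That lowers the count of 82, so 359 is no fair reference for it. The replicate numbers pair these groups. With the number as a block 0 genes passed and 137 had an unadjusted p under 0.05. With these 6 arrays alone the counts were 0 and 245, and with both 0 and 544 (smallest adjusted p = 0.534). The 544 of the fit with both lay above 359, though none passed the adjustment. Without replicate 1 of every group the counts were 0 and 292. Array quality weights called 2 genes, CIC (-1.45 ± 0.24) and RNASEH1 (-0.75 ± 0.13), both with an adjusted p of 0.0468. The arrays of both groups did not overlap in 675 genes (9.40%, where chance gives 10%).

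Ribosomal protein genes lay higher after irradiation in the eIF4E precipitates, in 46 of 53 members by a median of 0.12 (camera, adjusted p = 3.70e-06; adjusted p = 0.866 with an estimated correlation), but the median was -0.01 (adjusted p = 0.668) after quantile normalization. No member passed by itself, with 0 called over all genes and 0 adjusted over the list alone, and RPL3 (0.30) and RPS10 (0.28) had the smallest p. By replicate number the medians were -0.01, 0.27 and 0.11, and without untreated eIF4E replicate 2 the list did not pass (adjusted p = 0.904). The Alu signal of the same arrays also rose in each number, from 16839 to 18476, 13482 to 16569 and 14963 to 17728. Without pairing its difference had an exact permutation p of 0.2, and whether it bears on the list was not tested. DNA replication genes were above 0 in 35 of 45 members by a median of 0.08 (adjusted p = 0.0420; adjusted p = 0.440 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. That call was lost without replicate 1 of every group (adjusted p = 0.137) and without any of 5 single arrays: untreated eIF4E replicates 1 and 3 (adjusted p = 0.150 and 0.242) and irradiated eIF4E replicates 1, 2 and 3 (adjusted p = 0.0666, 0.0748 and 0.128). Targets of p53 had a median of -0.01 (adjusted p = 0.948).

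The same comparison in IgG precipitates gives the background of the irradiation effect. CCDC106, a coiled-coil protein, had the smallest p, at 1.67 ± 0.27 (adjusted p = 0.0910 by limma, n = 3 a side), with signals of 6.18 ± 3.2 and 54.2 ± 2.37. The former was below the 24.5 ± 7.66 of genes not expressed in this cell type, so the size depends on the pseudocount. Next was AHNAK, a large scaffold protein, at 1.01 ± 0.18 (adjusted p = 0.140). TRIO, a guanine nucleotide exchange factor, was at 0.84 ± 0.17 and at -0.18 as the mean of its probe sets. DUSP7, a MAP kinase phosphatase, was at -0.58 and BRCA1 at 0.80 ± 0.20 (adjusted p = 0.613). With limma 0 genes passed, and 475 had an unadjusted p under 0.05 (295 higher, 180 lower) where chance gives 359. The shared spread gave a median SE of 0.194, against 0.220 from these 6 arrays alone. That raises the count of 475, so 359 is no fair reference for it. The number of genes passing was 0 with the replicate block (642 unadjusted), with these 6 arrays alone (276) and without replicate 1 of every group (576). CCDC106 passed without a variance trend (adjusted p = 0.000817) and with probe set means (0.0151), and CTSV, a lysosomal protease, passed without untreated IgG replicate 1 (2.52 ± 0.32, adjusted p = 0.00937), from an untreated IgG signal of 49.3 ± 68.8 over all 3 arrays. That signal is not clear of the 24.5 ± 7.66 of genes not expressed in this cell type, so this size too depends on the pseudocount. The arrays did not overlap in 623 genes (8.68%, where chance gives 10%).

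In the IgG precipitates 3 repair and replication lists lay higher after irradiation: DNA replication (35 of 45 members above 0, median 0.07, adjusted p = 0.00609), homologous recombination and Fanconi anaemia (23 of 29, median 0.10, adjusted p = 0.0430) and end joining (7 of 9, median 0.24, adjusted p = 0.0430). Each had an adjusted p = 0.146 with an estimated correlation, and none passed without replicate 1 of every group (adjusted p = 0.228, 0.275 and 0.275). Over all genes 0 members passed, and adjusted over the list alone 0, 1 and 1 did. PRKDC, the kinase of end joining, was at 1.04 and TP53BP1, which favours end joining over resection, at 0.86, neither past the threshold over all genes. All 3 calls were lost without untreated IgG replicate 1 (adjusted p = 0.0914 for each). The recombination call was also lost without untreated IgG replicate 2 (0.0985) or irradiated IgG replicate 1 (0.112) or 3 (0.0808). The end joining call was lost without irradiated IgG replicate 1 (0.112), and both calls after centring (0.0515). The median signal of genes not expressed in this cell type was 24.5 ± 7.66 in untreated and 13.7 ± 0.319 in irradiated IgG (exact permutation test, two-sided, p = 0.1, the smallest that 3 arrays against 3 allow). Ribosomal proteins had a median of -0.06 (adjusted p = 0.226) and passed without untreated IgG replicate 2 (0.0446) or 3 (0.00981) or irradiated IgG replicate 1 (0.00760).

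**Figure D4:**
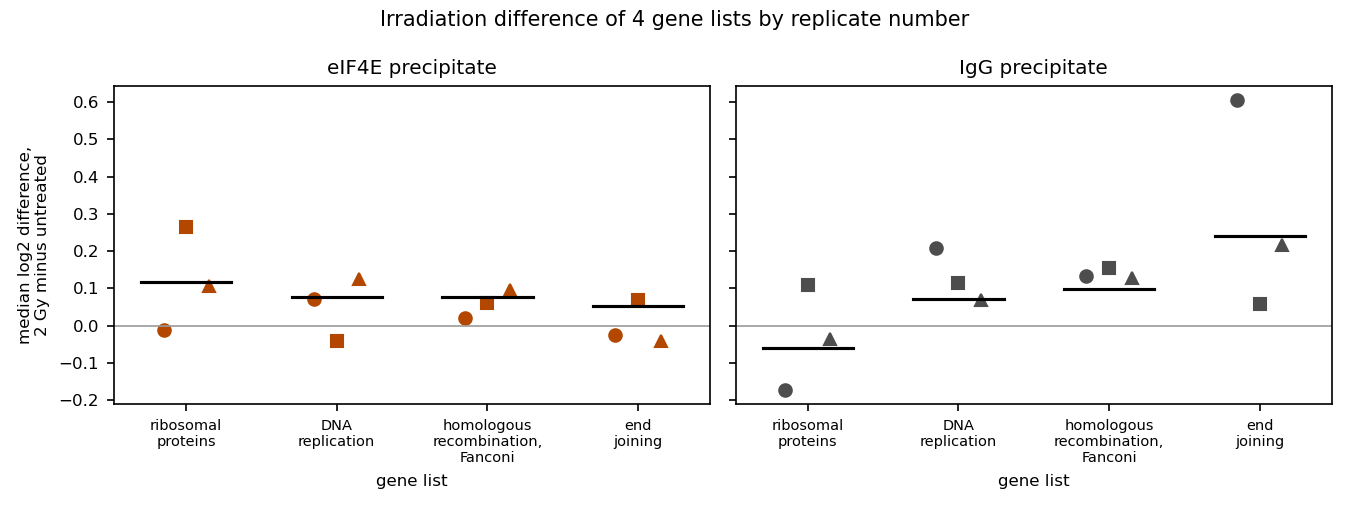
Median log2 difference of irradiated against untreated cells for 4 gene lists, by replicate number (points) and over all arrays (bar), in eIF4E and IgG precipitates. The ribosomal protein medians of eIF4E are -0.01, 0.27 and 0.11 for numbers 1, 2 and 3, and the median over all arrays, 0.12, becomes -0.01 after quantile normalization.

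The difference between both irradiation effects was tested as an interaction. DIP2A had the smallest p on the higher side, at 1.62 ± 0.38, and CCDC106 on the lower side, at -1.60 ± 0.38, and neither passed. With limma 0 genes passed (smallest adjusted p = 0.999) and 216 had an unadjusted p under 0.05, while the replicate block gave 0 and 304. The ribosomal protein list passed, with 45 of 53 members above 0 and a median of 0.15 (adjusted p = 1.23e-04; adjusted p = 0.896 with an estimated correlation), but its median was 0.03 (adjusted p = 0.983) after quantile normalization, with 0 members called over all genes and 0 adjusted over the list alone. Its call was lost without untreated IgG replicate 1 (adjusted p = 0.805), irradiated IgG replicate 3 (0.367) or untreated eIF4E replicate 2 (0.650). Across genes, the irradiation effects of both precipitates correlated at r = 0.0875 (rho = 0.106), with the same sign in 53.4% of genes.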

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

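No test in this part was chosen after its own result was seen, but those on the rise of ribosomal proteins followed from its call. The replicate number left out there was the one with the largest shift. At the preset correlation, the irradiation effect on ribosomal protein genes differed between eIF4E and IgG precipitates, by a median interaction of 0.149 (log2, camera, adjusted p = 1.23e-04). It lost the call with an estimated correlation (adjusted p = 0.896) and after quantile normalization (median 0.03, adjusted p = 0.983). It was singled out because a test of the difference itself passed. Its call was lost without untreated IgG replicate 1 (adjusted p = 0.805), irradiated IgG replicate 3 (0.367) or untreated eIF4E replicate 2 (0.650).

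The rise of ribosomal proteins within eIF4E precipitates, by 0.12, was weighed against their brightness and against 1 replicate number. Among 10000 random lists matched on mean signal the list lay at percentile 70.5, with matched medians of 0.08 to 0.14 (95% range), so signal level may account for it. Without number 2 the median was 0.05, at percentile 29.4 of matched lists, which decides nothing about that number because the list lay within the matched range with all 3. In single numbers, given as description only, the list lay at percentile 6.3, 99.96 and 41.9 for 1, 2 and 3. Number 2 alone, at 0.27, thus lay above its matched range of 0.15 to 0.24. In IgG the list's median of -0.06 lay within its matched range of -0.09 to 0.03 (percentile 19.1). The matched lists themselves had a median of 0.11 in eIF4E and -0.04 in IgG. The interaction of ribosomal protein genes was not set against matched lists, and signal level may account for it too. An effect of irradiation on these genes stays undecided, since the call at the preset correlation was lost with an estimated correlation and after quantile normalization.

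Further signals lay outside the gene tests. Of 664 probe sets with no named gene, 454 differed between eIF4E and IgG (limma, 184 higher and 270 lower, median -0.18), 368 in untreated and 356 in irradiated cells, and 0 changed with irradiation in eIF4E (16 at an unadjusted p under 0.05), in IgG (61) or in the interaction (35). The Alu probe set was 2.70-fold brighter on IgG than on eIF4E arrays, and poly-A control transcripts were at least 65.9-fold brighter, as they were near background on eIF4E arrays. All 6 IgG arrays exceeded all 6 eIF4E arrays in both.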

How the results depend on the processing

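Scaling to hybridization or poly-A controls, omission of replicate 1 of every group, and the block combined with only the groups compared were chosen after seeing the data. Of the named genes' values under the alternatives fixed in advance, 5325 kept direction and call, 49 lost the call, 19 gained it and 12 changed sign; the cause was not tested unless stated. Genes called with eIF4E against IgG ranged, with 1 array left out, from 3752 to 4472 in untreated cells, 3771 to 4348 in irradiated cells and 4860 to 5062 for their mean, and the irradiation counts from 0 to 0 in eIF4E, 0 to 1 in IgG and 0 to 0 for the interaction. Under the other settings fixed in advance the counts stayed between 3341 (fewer genes, at the 60th percentile filter) and 7595 (each of 10566 probe sets tested by itself). Rescaling moves every gene alike, which fixes these counts: hybridization controls gave 7102 and 7086 genes, all higher, in untreated and irradiated cells, and poly-A controls 7178 and 7178. Irradiation calls rose to 2 genes in eIF4E with array quality weights and to 1 in IgG without the variance trend, and 1 with probe set means. Lists called ranged, with 1 array left out, over 6 to 7, 5 to 6 and 5 to 7 for the antibody comparisons, 1 to 5 for irradiation in eIF4E (1 without untreated eIF4E replicate 3, 5 without its replicate 1, when oxidative phosphorylation was among them at an adjusted p of 2.59e-04), 0 to 6 in IgG (0 without untreated IgG replicate 1, 6 without its replicate 2) and 0 to 1 for the interaction. Quantile normalization left 1 list for irradiation in eIF4E and 0 for the interaction, omission of replicate 1 of every group left 0 in IgG, and an estimated correlation left 0, 0, 0, 0, 0 and 0 in the 6 comparisons. The correlation of the antibody differences was 0.927 and 0.950 with pseudocounts of 1 and 64, 0.822 without the filter, 0.965 with the 60th percentile filter and 0.918 to 0.939 with 1 array left out. That of the irradiation effects was 0.0222 without the filter, 0.137 with the higher filter and 0.00525 to 0.147 with 1 array left out. CHEK1 over both treatments changed sign with quantile normalization (0.0291), centring (0.106), probe set means (0.0825) and without untreated (0.000586) or irradiated IgG replicate 3, ranging from -0.114 to 0.0514 over omissions, and in irradiated cells from -0.0499 to 0.281. VEGFA changed sign with probe set means (0.324 in irradiated cells, 0.159 over both), as did TRIO (-0.176 for irradiation in IgG, 0.176 for the interaction), and ACTB in irradiated cells ranged from -0.224 to 0.382 over omissions. With the replicate block 4465, 4486, 5244, 0, 0 and 0 genes and 7, 5, 6, 2, 4 and 1 lists were called in the 6 comparisons; the block added mitosis in untreated cells (adjusted p = 0.0497), heat shock proteins for irradiation in IgG (0.0442) and CDKN1A over both treatments (0.00449) and in irradiated cells (0.0112), and changed no other call of a list or named gene. Only the eIF4E groups were treated as paired, so elsewhere the block shares a number only. Genes under the filter signal of 57.4 could not be tested.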

Other observations

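Tests on gene families, on fragmented RNA and on RNA input were chosen after the results were seen. Messengers of mitochondrial ribosomal proteins, which translate the subunits encoded in mitochondrial DNA, were relatively higher with eIF4E than with IgG, as were those of oxidative phosphorylation. Of 29 genes of the large mitochondrial subunit (MRPL), 28 were higher and 0 lower, with a median of 1.18 over both treatments (camera over 36 families, adjusted p = 3.30e-10; adjusted p = 0.0758 with an estimated correlation). MRPL34 was higher by 2.26 ± 0.15 and MRPL13 by 1.92 ± 0.12 (log2, SE, 6 arrays a side). Of 19 genes of the small subunit (MRPS), 18 were higher and 1 lower (median 0.97, adjusted p = 4.45e-06; adjusted p = 0.125 with an estimated correlation), from MRPS17 at 2.24 ± 0.11 to MRPS27 at -0.79 ± 0.10. RNA polymerase subunits (POLR) were higher in 15 and lower in 4 of 25 (median 0.77, adjusted p = 0.0114; adjusted p = 0.157 with an estimated correlation), with POLR2E at 1.93 and POLR2B, the second largest subunit of polymerase II, at -1.12.

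Families of motor, helicase and pore proteins lay on the other side, and all of these families moved with the 2.70-fold higher Alu signal and 2.95-fold higher actin 3'/5' ratio of the IgG arrays. Kinesins (KIF), motors of the microtubule, were lower in 16 and higher in 1 of 19 (median -0.87, adjusted p = 0.00216; adjusted p = 0.0795 with an estimated correlation), with KIF5B at -1.83 ± 0.09, KIF11 at -1.58 ± 0.12 and KIF22 at 1.06 ± 0.15. DEAD-box helicases (DDX) were lower in 15 and higher in 1 of 22 (median -0.75, adjusted p = 0.0152; adjusted p = 0.157 with an estimated correlation), with DDX21 at -1.82. Nucleoporins (NUP) were lower in 13 and higher in 3 of 20 (median -0.77, adjusted p = 0.0219; adjusted p = 0.486 with an estimated correlation), and ubiquitin proteases (USP) in 20 and 2 of 26 (median -0.60, adjusted p = 0.0193; adjusted p = 0.0986 with an estimated correlation), with USP9X at -1.83. Secretory pathway SEC genes were lower in 14 and higher in 3 of 19 (median -0.88, adjusted p = 0.0317; adjusted p = 0.182 with an estimated correlation). All genes named ZNF had 64 lower and 16 higher of 154 (median -0.30, adjusted p = 0.0484; adjusted p = 0.0795 with an estimated correlation), a call lost after quantile normalization (adjusted p = 0.106) and centring (0.0509), and TMEM genes had 36 higher and 15 lower of 65 (median 0.49, adjusted p = 0.0219; adjusted p = 0.571 with an estimated correlation). The families kept the sign of their median under quantile normalization and centring. None of the families, mitochondrial ribosomal proteins included, was set against lists matched on gene length and signal. Gene length therefore stays open as a cause for them. The Alu signal and actin ratio separate the same arrays as the antibody, so moving with them cannot be told apart from it.

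Long genes were lower with eIF4E against IgG: in 4 equal bins of genomic gene length (medians 6693, 21040.5, 46947.5 and 129171 bases) the median log2 difference was 0.48, 0.08, -0.25 and -0.66, and across 7177 genes Spearman's rho was -0.470 (95% bootstrap range over genes -0.488 to -0.451, and -0.471 to -0.416 in single replicate numbers). Fragmented or 3'-biased RNA on IgG arrays, where the actin 3'/5' ratio was 2.96 to 5.38 against 1.33 to 1.53 with eIF4E, was taken to put rho above 0. The rho seen was -0.470, but it decides nothing on this cause. Gene length is not transcript length, and the places of probe sets within transcripts, on which the expected sign depends, were not known. Such RNA cannot be told apart from the antibody either. Unspliced or genomic sequence in IgG precipitates stays open: probe sets with no gene had a median of -0.175, at percentile 1.52 of 10000 lists of named probe sets matched on signal (-0.168 to -0.004), and may hold such sequence. Lower RNA input with IgG cannot be told apart from the antibody, because the poly-A controls, at least 65.9-fold brighter with IgG, separate the same arrays, and binding of eIF4E to shorter messengers remains an untested hypothesis.

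Lists that stood apart in eIF4E against IgG were set against 10000 lists matched on gene length and mean signal (95% ranges). The matched lists argue against length and signal as the whole cause for oxidative phosphorylation (0.89 against -0.01 to 0.53, percentile 100), mesenchymal genes (-1.0 against -0.50 to 0.22, percentile 0), zinc fingers (-0.48 against -0.36 to 0.26, percentile 0.23) and ribosomal proteins (-0.30 against 0.09 to 0.59, percentile 0). The ribosomal median became 0.03 after quantile normalization and still lay low among matched lists (median 0.39, percentile 0.1). For proteasome subunits (percentile 95.5) and histones (percentile 79.8) length and signal may account for the shift. Transcript length, input and background binding to IgG were not separated from the antibody, so a preference of eIF4E for respiratory messengers is only a hypothesis.

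Other splits of the arrays bear on the counts. For the mean of both treatments 1 of 100 splits, the real one with 5078 genes, gave as many, and the highest other gave 2449, so chance can be excluded. With 10 splits in untreated and 10 in irradiated cells a share under 0.05 cannot be reached; the real split alone (1 in each) gave 4230 and 4273 genes, and the highest other 0 and 0. For irradiation, counted at an unadjusted p under 0.05, 6 of 10 splits gave as many as the real 82 genes in eIF4E (highest other 335) and 6 of 10 as the real 475 in IgG (highest other 1098), again too few splits for a share under 0.05. The 4 splits that kept both replicate 1 arrays together called 214 to 335 genes in eIF4E, where the 4 splits that part all numbered pairs gave at most 83 and 2 of them as many as the real one. This points to a structure of the eIF4E arrays by replicate 1. In IgG the former gave 497 to 1098 and the highest other of the latter 699, so their ranges overlap. For the interaction 74 of 100 splits gave at least the real 216 (highest other 1208). Of these, 36 part all numbered eIF4E pairs as the real one does, and 20 of them gave at least 216 (highest other 681), so chance cannot be excluded. The other 64 had a median of 320.5 genes, against 228 for the 36 without the real split.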
